A study of Homo sapiens with 51 samples.

How the data were processed

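Gene expression was measured by RNA sequencing of poly(A) RNA (stranded mRNA libraries) in 51 libraries of human blood granulocytes. Bulk normal-density neutrophils (NDN) came from people with lupus and from healthy controls, and lupus low-density granulocytes (LDG) came from the mononuclear layer by negative selection with magnetic beads. A second set of lupus cells was sorted by flow cytometry with antibodies against CD10, CD14 and CD15 into CD10-positive NDN (here sorted NDN), CD10-positive LDG and CD10-negative LDG. Groups were taken from the sample titles and characteristics, and the series describes lupus NDN as autologous to the LDG. The bulk table held 33 libraries, 27 of sequencing run 1 and 6 of run 2 (3 healthy NDN, 2 lupus NDN and 1 mat LDG). The sorted table held 18 libraries of run 3, with 3 labelled LE and 3 PPAR per fraction.

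Per the labels, the authors processed reads with bcl2fastq 2.17.1, TopHat2 2.1.1 and Partek 6.6 on the human genome build hg19, and the counting settings and gene annotation were not given. Values in both deposited tables are RPKM, read counts scaled by gene length and library size, estimated by the authors with fractional reads. The deposited bulk table is in RPKM with some cells of other content, since a question mark stands in every library of a run for genes missing from that run. These were read as 0: 319 genes in run 1, whose highest mean in the other run was 1.32 RPKM, and 2037 genes in run 2, whose highest mean in the other run was 0.416 RPKM. The tables list 24643 and 26184 genes. Y-linked genes and the genes of X inactivation were left out of every table and test (103 and 76 genes). No pair of libraries shared more than 0.0146% identical values among genes above an RPKM of 1.

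Read counts or totals were not used here. Depth relative to the deepest library of a table was read from the spacing of the lowest values, and ran from 0.228 to 1 in the bulk and from 0.282 to 1 in the sorted table. Its precision is set by the peak of the ratio between libraries, at least 12 and 29 times its background. Libraries in doubt were defined after the data were seen as those with hemoglobin above 5000 RPKM, a relative depth under 0.3 or, in the bulk table, mitochondrial rRNA above 15000 RPKM. They were 3 of 11 healthy NDN (3 by hemoglobin, 1 of them also by depth), 3 of 8 mat LDG (3 by mitochondrial rRNA, 1 of them also by hemoglobin) and 1 of 6 CD10-negative LDG (by depth), and stayed in the main tests.

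Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust) on log2(RPKM + 1), with genes at an RPKM of 0.5 or more in at least as many libraries as the smaller group holds, and a Benjamini-Hochberg adjusted p under 0.05 for a call. Each comparison used the libraries of its 2 groups. PPAR was compared with LE in 1 fit of 6 groups. The comparisons, tests and gene lists were chosen before the data were examined. The 28 gene lists were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Lists with fewer than 5 tested members got no list test, and the list of mitochondrially encoded transcripts had 0 tested genes in either table. Members of a list were counted by the test over all genes and after adjustment over the list alone. Some lists share genes, such as FPR1 and ALPL of the gelatinase granule and mature receptor lists, and some marker genes of other cells are also expressed by neutrophils (CD14, CSTA, RNASE2). Gene symbols were matched through the synonyms of a GRCh38 annotation, and no coordinates were used, since the genome builds differ. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

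The named genes followed a rule: MME in each of 7 comparisons, with CD14 and FUT4 in the sorted table, the 5 called genes with the largest rise and the 5 with the largest fall among those with a mean RPKM of at least 2 in a group, and the 2 called members with the largest change of each called list. For PPAR against LE they were the 3 called genes with the largest rise and fall. Immunoglobulin, T cell receptor, HLA and KIR genes, commonly deleted genes and unnamed or small RNA genes were not named by rule. List members named beyond the rule were chosen after their values were seen, as were genes that were not called.

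Replicate numbers of the titles were checked as pairs by the correlation of a library's deviations from its group between fractions of the same number. For the sorted libraries, 6 of 6 pairs were above 0.1 in each case. Medians were 0.48 for CD10-negative with CD10-positive LDG, 0.57 for CD10-positive LDG with NDN and 0.27 for CD10-negative LDG with NDN. The block was tried only as an alternative, so sorted counts and p-values ignore this pairing unless the block is named. Among the bulk libraries, 9 of 11 pairs of LDG and lupus NDN were above 0.1 (median 0.34, lowest −0.35), against a median of −0.071 for different numbers. Most pairs agreed but not all, so the numbers were not taken as pairs in the main fit, which may ignore a real pairing. Lupus and healthy NDN come from different people, and 4 of 11 of their shared numbers were above 0.1 (median −0.22). A block over these numbers has no pairing behind it, and the same holds for LDG against healthy NDN. The other alternatives were a pseudocount of 0.1, no filter or an RPKM of 2 or more, size factors by median of ratios, quantile normalization, each library scaled to the same sum, eBayes without trend or robust, 1 fit over all groups of a table, the sequencing run as a term, each run, each LDG label and each donor label alone, groups of 3 without each library in turn and, added after the data were seen, the libraries in doubt left out.

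The tests were tried on simulated data. Each gene had the mean and spread of the second group of a comparison on both sides, and genes were drawn independently. The shares recovered hold for that spread, which the first group need not have. The mean level of interferon-stimulated genes, for instance, had an SD of 1.6 in lupus and 0.487 in healthy NDN. For such genes the recovery may be overstated. With a log2 change of 1, 88% of changed genes were recovered for lupus against healthy NDN, 80.4% for LDG against lupus NDN, 84.9% for LDG against healthy NDN, 48% for CD10-negative against CD10-positive LDG, 76.2% for CD10-positive LDG against NDN, 71.7% for CD10-negative LDG against NDN and 64.4% for PPAR against LE in CD10-positive LDG. For imm against mat LDG it was 5.45%.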

Results

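The deposited tables hold gene-level RPKM values of lupus and healthy neutrophils, in 33 bulk and 18 flow-sorted libraries. The bulk libraries are healthy normal-density neutrophils (NDN, n = 11), lupus NDN (n = 11) and lupus low-density granulocytes (LDG), the latter labelled mat (n = 8) or imm (n = 3). The sorted libraries are lupus NDN, CD10-positive LDG and CD10-negative LDG, with 6 of each. The labels do not say what mat, imm, LE or PPAR stand for, and mat and imm may have been assigned from the transcriptomes themselves. The 2 tables were normalized separately, so genes were tested only within a table. Between 7383 and 10411 genes lay above an RPKM of 1 in each bulk library, and between 8077 and 11572 in each sorted library. Separate donors are only implied by the sample titles, so p-values measure the spread between these samples, which may be technical. Changes are differences of log2(RPKM + 1) with adjusted p-values from limma, a scale that understates changes of genes with low values. Values after ± are SDs.

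Lupus NDN carried a higher interferon signature than healthy NDN on average, and it was uneven between the lupus libraries. Monocyte markers and inflammatory cytokine genes also lay higher, while T cell markers, eosinophil markers and ribosomal protein genes lay lower. None of these list calls, that of the interferon genes included, held with an estimated correlation between genes. No single gene passed the adjusted threshold. MME, which encodes the CD10 of mature neutrophils, did not differ detectably. Of 11171 genes tested with limma, 0 were called and 725 had an unadjusted p under 0.05. The median of 48 interferon-stimulated genes was 1.06 (adjusted p 1.8e-47 for the list, adjusted p = 0.068 with an estimated correlation between genes), and 0.95 within sequencing run 1, and 24 of the 48 passed when adjusted over the list alone. The interferon score, a mean of log2(RPKM + 1) over the list, was 3.8 ± 0.487 in healthy NDN, with a range of 3.11 to 4.52. In lupus NDN it was 5.01 ± 1.60, with 6 of 11 libraries at 5.91 or more and 5 at 4.18 or less. A permutation of the labels gave p = 0.028 for this difference of 1.21, for a list picked after its result was seen. IFI44L averaged 62.5 ± 64.2 RPKM in lupus against 5.76 ± 6.57 in healthy NDN (log2 2.31, SE 0.77, adjusted p 0.715), and RSAD2 161 ± 170 against 13.7 ± 12.3 (log2 2.22, SE 0.83, adjusted p 0.715). IFIT3 (log2 1.47) and IFIT2 (log2 1.05) had the same direction and were not called either.

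Among the other lists in lupus NDN, 13 monocyte markers had a median of 0.60 (adjusted p 1.1e-13, adjusted p = 0.068 with an estimated correlation), with 6 passing over the list alone. VCAN averaged 8.10 ± 8.73 against 1.39 ± 1.07 RPKM (log2 1.45, SE 0.40, adjusted p 0.715) and CPVL had a log2 difference of 1.29, neither called. Inflammatory cytokines and NF-kB targets had a median of 0.35 (adjusted p 4.6e-11, adjusted p = 0.068 with an estimated correlation), and toll-like receptors and nucleic acid sensors 0.24 (adjusted p 9.8e-08, adjusted p = 0.068 with an estimated correlation). Inflammasome genes stood at 0.27 (adjusted p 1e-06, adjusted p = 0.1 with an estimated correlation) and specific granule proteins at 0.27 (adjusted p 1.6e-06, adjusted p = 0.16 with an estimated correlation). Gelatinase granule and secretory vesicle proteins stood at 0.24 (adjusted p 6.4e-06, adjusted p = 0.16 with an estimated correlation) and Fc and complement receptors at 0.23 (adjusted p 9.2e-06, adjusted p = 0.2 with an estimated correlation). Smaller medians were those of immediate early genes (0.16, adjusted p 5.9e-07, adjusted p = 0.17 with an estimated correlation), chemotaxis and actin genes (0.13, adjusted p 2.7e-05, adjusted p = 0.36 with an estimated correlation) and receptors of mature neutrophils (0.13, adjusted p 0.0015, adjusted p = 0.36 with an estimated correlation). Platelet markers (0.14, adjusted p 0.0021, adjusted p = 0.36 with an estimated correlation) and NADPH oxidase genes (0.16, adjusted p 0.011, adjusted p = 0.36 with an estimated correlation) were called higher too. Others were B cell markers (0.10, adjusted p 0.012, adjusted p = 0.24 with an estimated correlation), dendritic cell markers (0.28, adjusted p 0.021, adjusted p = 0.1 with an estimated correlation) and azurophilic granule proteins (0.16, adjusted p 0.039, adjusted p = 0.52 with an estimated correlation). Over their own list alone, 3 immediate early genes and 1 toll-like receptor gene passed. On the lower side, 79 ribosomal protein genes had a median of −0.52 (adjusted p 1.1e-13, adjusted p = 0.36 with an estimated correlation). The median was −0.58 for 18 T cell markers (adjusted p 1.8e-05, adjusted p = 0.36 with an estimated correlation) and −0.66 for 15 eosinophil markers (adjusted p 0.00036, adjusted p = 0.36 with an estimated correlation). CD3E (log2 −0.58), RPL10A (log2 −0.73) and the eosinophil protease gene PRSS33 (log2 −1.20) had that direction without a call. Erythroid markers (median −0.76, adjusted p 0.053), NK cell markers (−0.37, adjusted p 0.068; within run 1 −0.43, adjusted p 0.0016, and 0.044 with the replicate block, adjusted p = 0.5 with the block and an estimated correlation), early precursor, cell cycle, protein folding and oxidative phosphorylation genes were not called as lists. Dendritic cell markers and receptors of mature neutrophils lost their call within run 1 (adjusted p 0.11 and 0.081), and dendritic cell markers also without the libraries in doubt (adjusted p 0.095). With quantile normalization the calls of azurophilic granule (0.11), NADPH oxidase (0.16), chemotaxis (0.061) and mature receptor lists (0.24) were lost. The azurophilic call was lost under 5 further alternatives, with adjusted p from 0.05 with the run as a term to 0.53 at an RPKM of 2 or more. MME averaged 71.9 ± 39.4 RPKM in lupus and 55.1 ± 28.2 in healthy NDN (log2 0.23, SE 0.38, adjusted p 0.876).

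Lupus LDG differed from lupus NDN by higher granule protein and platelet genes and by lower markers of T cells, NK cells and eosinophils, together with lower ribosomal protein genes. As lists, only the platelet and T cell calls held with an estimated correlation (adjusted p 0.028 each), the others having an adjusted p from 0.058 to 0.22. The mature neutrophil receptors were not called. Interferon-stimulated genes, higher in lupus NDN than in healthy NDN as a list, were not called between LDG and NDN of lupus either. MME did not differ detectably (log2 −0.27, SE 0.45), with an error that leaves room for a 2-fold fall. Of 10651 genes tested, 1353 were called, 209 higher and 1144 lower in LDG (15.4% higher), and 141 and 410 of these changed at least 2-fold. The balance depended on scaling: the share higher was 29.1% with size factors and 33.5% with quantile normalization, as the median of all genes moved from −0.13 to −0.01 and 0.01. Within run 1 the count was 1218, and run 2 held 1 LDG library, itself in doubt.

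The rise in granule transcripts covered 12 of 14 azurophilic granule genes, which encode the contents of the earliest granules (12 over the list alone, median 2.21, adjusted p 1.1e-12, adjusted p = 0.1 with an estimated correlation). Within run 1 that median was 1.86, and without the libraries in doubt it was 1.43. Of 17 specific granule genes 11 rose (13 over the list alone, median 1.93, 1.88 within run 1, adjusted p 3.4e-19, adjusted p = 0.058 with an estimated correlation). LTF, encoding lactoferrin, averaged 460.8 ± 645 RPKM in LDG and 19.5 ± 25.2 in NDN (log2 4.13, adjusted p 9.59e-05), and LCN2 464.8 ± 670.4 against 20 ± 21.6 (log2 3.89, adjusted p 0.000109). MS4A3 (log2 2.72, adjusted p 0.000568) and AZU1 (log2 2.69, adjusted p 0.0039) rose too, whereas CTSC and RNASE3 were not called. All 17 platelet markers rose (17 over the list alone, median 3.82, 3.45 within run 1, adjusted p 1.4e-34 and 0.028 with an estimated correlation). With the replicate block and an estimated correlation, the calls of platelet and T cell markers were lost (adjusted p 0.099 for each), and gelatinase granule genes were called at the preset correlation (0.039, adjusted p = 0.52 with an estimated correlation). PPBP averaged 319.9 ± 393.6 against 4.22 ± 6.66 RPKM (log2 5.23, adjusted p 2.39e-05) and TUBB1 168.7 ± 213 against 2.61 ± 3.05 (log2 4.84, adjusted p 5.24e-06), followed by PF4 (log2 4.63), GP1BB (log2 4.36) and SDPR (log2 4.17). Of 15 cell cycle genes 3 rose, RRM2 (log2 1.14), E2F1 (log2 1.11) and AURKB (log2 0.74), also 3 over the list alone (median 0.26, adjusted p 0.00011, adjusted p = 0.39 with an estimated correlation). E2F1 lost its call within run 1 (adjusted p 0.0586) and RRM2 with mat LDG alone (0.0507). ARG1 was the 1 gelatinase granule gene of 16 to rise (log2 1.72) and GATA2 1 of 3 basophil markers (log2 1.88). The lists of 3 B cell and 3 plasma cell markers were too short for a list test.

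**Figure D1:**
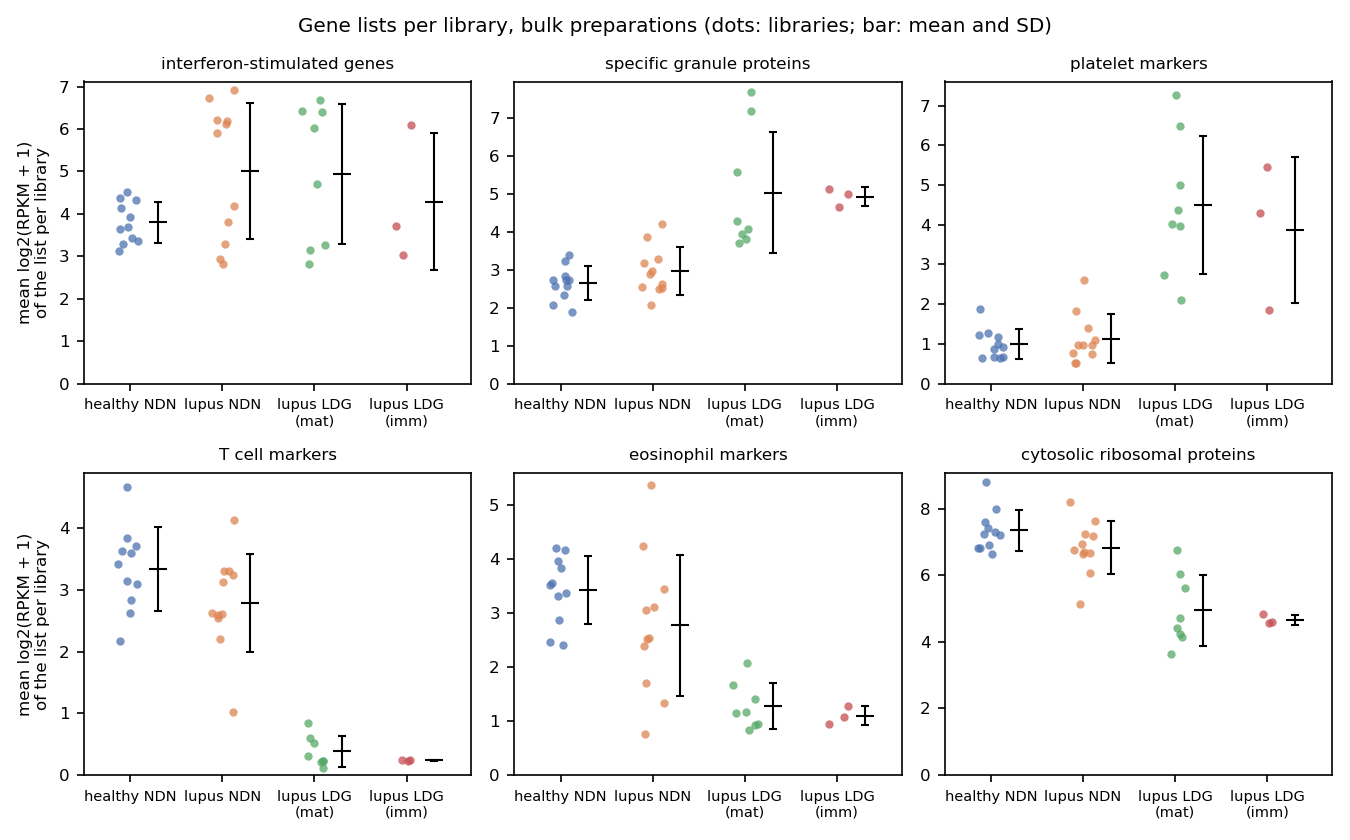
Mean log2(RPKM + 1) of 6 gene lists in the bulk libraries, by group, with 1 dot per library and bars for the mean and SD. Platelet markers averaged 0.992 in healthy NDN and 4.49 in mat LDG, and T cell markers 3.34 and 0.383.

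T cell markers were nearly absent from the bulk LDG. All 14 fell (14 over the list alone, median −2.45, −2.46 within run 1, adjusted p 2.5e-28 and 0.028 with an estimated correlation). CD3E stood at 0.557 ± 0.608 against 37.6 ± 23.8 RPKM (log2 −4.41, adjusted p 1.63e-08), CD3D at log2 −3.84 and the lymphocyte gene CD52 at 2.46 ± 2.23 against 108.1 ± 129.7 (log2 −4.68, adjusted p 5.83e-08). Of 12 NK cell markers 9 fell (median −2.40, adjusted p 2.5e-09, adjusted p = 0.059 with an estimated correlation), GZMH by 3.46 and GZMA by 3.35 among them. Of 10 eosinophil markers 7 fell (9 over the list alone, median −1.84, adjusted p 2.7e-06, adjusted p = 0.22 with an estimated correlation), led by PRSS33 (log2 −3.28) and ALOX15 (log2 −3.14). Of 13 monocyte markers 6 fell (7 over the list alone, median −0.94, −1.13 within run 1, adjusted p 0.0064, adjusted p = 0.43 with an estimated correlation), CPVL by 2.18 among them. With imm LDG alone PRSS33 (adjusted p 0.0576), ALOX15 (0.0643) and CPVL (0.076) were not called. The monocyte list call was lost with imm LDG alone (0.06) and at an RPKM of 2 or more (0.13), and that of erythroid markers with no filter (0.89). Of 5 erythroid markers 4 fell (median −3.51, adjusted p 0.0043, adjusted p = 0.21 with an estimated correlation). HBA2, whose reads cannot be told from those of its near-identical copy HBA1, fell by 4.46 (adjusted p 0.00258) although its means, 253 ± 823.4 and 337.9 ± 312.4 RPKM, lay close together because few LDG libraries carried most of the LDG mean. HBB fell by 3.57. In run 2 alone HBA2 and HBB had the opposite sign.

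The ribosomal protein genes moved together with the lymphocyte markers. Of 79, 77 fell (79 over the list alone, median −1.96, −2.16 within run 1, adjusted p 6.2e-47, adjusted p = 0.1 with an estimated correlation). RPL23A averaged 16.9 ± 18 against 122.7 ± 68.5 RPKM (log2 −3.05, adjusted p 2.55e-05) and RPL10A fell by 3.04, and reads of this family can be shared with its pseudogenes. Of 30 genes for protein folding and translocation in the endoplasmic reticulum 16 fell (21 over the list alone, median −0.68, adjusted p 2.9e-09, adjusted p = 0.21 with an estimated correlation), CALR by 1.47 and PDIA4 by 1.43. Of 55 nuclear-encoded oxidative phosphorylation genes 19 fell (33 over the list alone, median −0.52, adjusted p 3.3e-08, adjusted p = 0.39 with an estimated correlation), COX6C by 1.41 and COX7C by 1.38. Inflammatory cytokines and NF-kB targets fell in 8 of 27 (12 over the list alone, median −0.84, adjusted p 7.2e-06, adjusted p = 0.25 with an estimated correlation). The chemokine gene CCL3 stood at 6.31 against 49.3 RPKM (log2 −2.65, adjusted p 7.51e-05), and NFKBIA at 191 against 1303 (log2 −2.41, adjusted p 0.00054). Immediate early genes fell in 7 of 23 (10 over the list alone, median −0.73, adjusted p 0.00052, adjusted p = 0.4 with an estimated correlation), DUSP2 by 2.18 and NR4A1 by 1.61. With imm LDG alone, which leaves 3 LDG libraries, NFKBIA (adjusted p 0.121), DUSP2 (0.163), NR4A1 (0.201) and COX6C (0.0737) were not called. Among 11 early precursor genes CLEC5A rose (log2 1.31) and CD81 (log2 −3.22), ITGA4 (log2 −1.73) and MYC (log2 −1.56) fell, with no list call (median 0.04, adjusted p 0.84). None of 23 mature receptor genes was called (median −0.16, adjusted p 0.55), CXCR2 (log2 −0.35), CXCR1 (log2 −0.16), CSF3R (log2 −0.08) and FCGR3B (log2 −0.22) included. MME averaged 59.3 ± 38 against 71.9 ± 39.4 RPKM (log2 −0.27, adjusted p 0.755). FUT4, the gene of an enzyme that can make the CD15 sugar and not of CD15 itself, had a log2 difference of 1.15 (adjusted p 0.0757). The lists of interferon-stimulated genes (median −0.22, adjusted p 0.37), gelatinase granule proteins (−0.06, adjusted p 0.072), inflammasome, toll-like receptor, Fc receptor, chemotaxis, NADPH oxidase and dendritic cell genes were not called. Without the libraries in doubt, 4 of these lists were called higher in LDG: interferon-stimulated genes (median 0.40, adjusted p 1.3e-05), gelatinase granule proteins (0.27, adjusted p 0.0091), mature receptors (0.14, adjusted p 0.014) and inflammasome genes (0.24, adjusted p 0.0069).

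**Figure D2:**
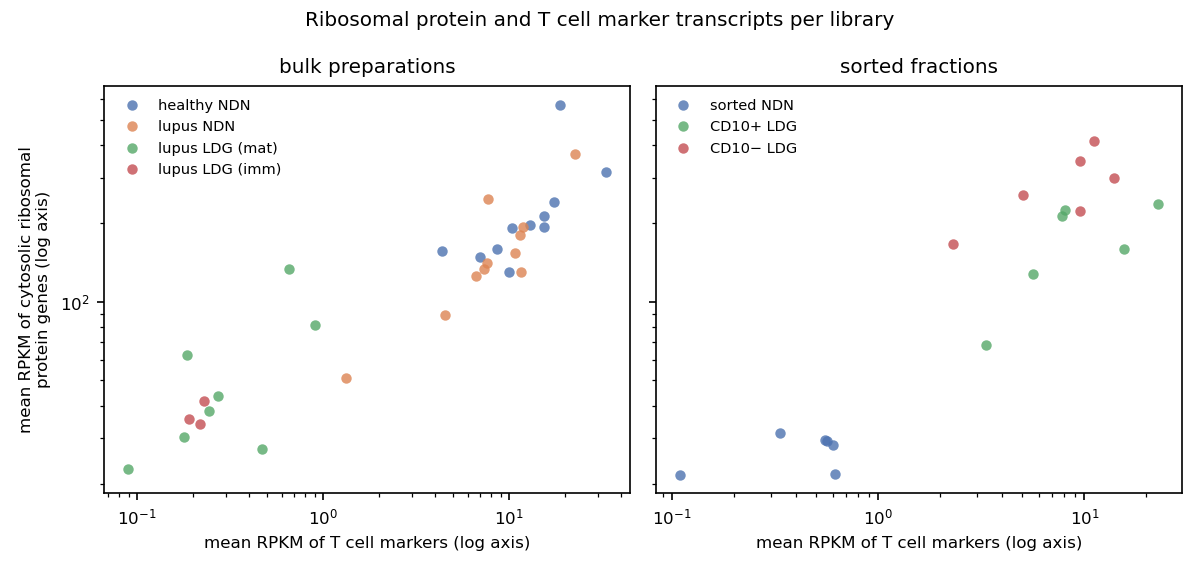
Mean RPKM of 79 ribosomal protein genes against mean RPKM of T cell markers on log axes, with 1 dot per library, for the bulk and sorted tables. Bulk LDG and sorted NDN lay low on both axes, at ribosomal means of 55.1 RPKM (mat), 37.1 RPKM (imm) and 27 RPKM, in tables that were normalized separately.

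Against healthy NDN, lupus LDG again had higher granule and platelet genes and lower T cell, NK cell, eosinophil and ribosomal protein genes. Interferon-stimulated genes were called higher as a list at the preset correlation (adjusted p = 0.21 with an estimated correlation). Of the others, azurophilic granule (0.092), NK cell (0.071) and ribosomal protein lists (0.088) were lost in the same way, while specific granule, platelet, T cell and eosinophil lists held (0.03 each). None held with the replicate block as well, but that block joins lupus LDG with NDN of different people by title number. A loss with it says little about these lists. The comparisons with healthy and with lupus NDN share the 11 LDG libraries, and no difference between them was tested. In both, the preparation of LDG cannot be told apart from the cells themselves. Of 10968 genes tested 2674 were called, 326 higher and 2348 lower (12.2% higher; 28.6% with size factors, 34% with quantile normalization, as the median of all genes moved from −0.19 to −0.01 and 0.02), and 181 and 674 of these changed at least 2-fold. Within run 1 the count was 2228. LTF rose from 10.8 ± 11.2 to 460.8 ± 645 RPKM (log2 4.79, adjusted p 1.96e-06), LCN2 rose by log2 4.63, MS4A3 by 3.07 and DEFA1B, whose reads cannot be told from those of DEFA1, by 2.85. Azurophilic granule genes rose in 11 of 13 (median 2.34, 2.03 within run 1, adjusted p 1.5e-11, adjusted p = 0.092 with an estimated correlation) while CTSC fell by 0.78. Specific granule genes rose in 15 of 17 (16 over the list alone, median 2.19, 2.11 within run 1, adjusted p 1.3e-22 and 0.03 with an estimated correlation). Gelatinase granule genes rose in 4 of 16 (median 0.13, adjusted p 8e-05, adjusted p = 0.1 with an estimated correlation), CD177 by 2.51 and ARG1 by 2.26. All 17 platelet markers rose (median 4.10, 3.65 within run 1, adjusted p 5.3e-33 and 0.03 with an estimated correlation), PPBP by 5.44, TUBB1 by 4.87 and PF4 by 4.77. With the replicate block and an estimated correlation, platelet, T cell and specific granule lists had an adjusted p of 0.12 and eosinophil markers 0.13.

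Interferon-stimulated genes had a median of 0.86 in LDG against healthy NDN (0.93 within run 1, 1.54 without the libraries in doubt, adjusted p 2.5e-16, adjusted p = 0.21 with an estimated correlation), with 4 of 48 called over all genes, 0 over the list alone. These were IFI44L (log2 2.31), PLSCR1 (log2 1.21), GBP1 (log2 1.02) and ZBP1 (log2 0.86). The call of IFI44L was lost with no filter (adjusted p 0.0701), libraries scaled to the same sum (0.0598), 1 fit over all groups (0.052), the run as a term (0.0739) and imm LDG alone (0.301). That of PLSCR1 was lost with no filter (0.0766), 1 fit (0.0788), the run as a term (0.081), within run 1 (0.1) and with mat (0.0545) or imm LDG alone (0.212). Cell cycle genes rose in 3 of 16 (1 over the list alone, median 0.18, adjusted p 0.0014, adjusted p = 0.4 with an estimated correlation), RRM2 by 1.17 and NUSAP1 by 0.80. NUSAP1 lost its call under 8 alternatives, among them a pseudocount of 0.1 (adjusted p 0.0589), no filter (0.0905), the run as a term (0.0695) and the libraries in doubt left out (0.141). The adjusted p of these 8 ran from 0.0552 without trend or robust to 0.176 within run 1. Inflammasome genes (median 0.26, adjusted p 0.00034, adjusted p = 0.19 with an estimated correlation) included NLRC4 (log2 0.88), and toll-like receptor genes (median 0.11, adjusted p 0.0014, adjusted p = 0.13 with an estimated correlation) TLR5 (log2 0.83) and IRAK3 (log2 0.68), while 1 toll-like receptor gene fell. Within run 1 NLRC4 (adjusted p 0.0848), TLR5 (0.121) and IRAK3 (0.0837) were not called, nor with mat LDG alone (0.0569, 0.0663 and 0.116). IRAK3 also lost its call with no filter (0.0604), the run as a term (0.0753) and without the libraries in doubt (0.0766), and TLR5 with 1 fit (0.0528) and imm LDG alone (0.0889). The lists of mature receptors (median −0.04, adjusted p 0.032, adjusted p = 0.6 with an estimated correlation) and Fc receptors (median −0.00, adjusted p 0.013, adjusted p = 0.4 with an estimated correlation) were called higher although their medians were just under 0. Both medians were above 0 under each of the 3 scalings tried, but with quantile normalization both list calls were lost (adjusted p 0.19 and 0.091), as they were with no filter (0.17 and 0.066) and with mat LDG alone (0.16 and 0.08). FCAR, an IgA receptor gene, rose by 0.68, a call lost with mat LDG alone (adjusted p 0.0638) and with imm LDG alone (0.0963). All 18 T cell markers fell (median −2.99, −3.12 within run 1, adjusted p 1.2e-31 and 0.03 with an estimated correlation), CD3E from 53.0 ± 31 to 0.557 ± 0.608 RPKM (log2 −5.00, adjusted p 9.9e-13), and CD52 fell by 5.19 and CD3D by 4.52. NK cell markers fell in 10 of 12 (median −2.83, adjusted p 8.2e-09, adjusted p = 0.071 with an estimated correlation), KLRB1 by 4.42 and GZMA by 3.93. Eosinophil markers fell in 12 of 14 (median −2.47, adjusted p 3.4e-15 and 0.03 with an estimated correlation), PRSS33 by 4.49 and ALOX15 by 3.76. Erythroid markers fell in 4 of 5 (median −4.98, adjusted p 0.0039, adjusted p = 0.13 with an estimated correlation), HBA2 by 5.75, HBB by 5.12 and HBA1 by 4.98, a list call lost with no filter (adjusted p 0.32). All 79 ribosomal protein genes fell (median −2.44, −2.67 within run 1, adjusted p 1.1e-47, adjusted p = 0.088 with an estimated correlation), RPL10A from 178.3 ± 103.9 to 19.1 ± 24.6 RPKM (log2 −3.77) and RPSA by 3.70. Protein folding genes fell in 21 of 30 (25 over the list alone, median −0.84, adjusted p 1.6e-08, adjusted p = 0.12 with an estimated correlation), CALR by 1.54 and PDIA4 by 1.52. Oxidative phosphorylation genes fell in 34 of 55 (44 over the list alone, median −0.67, adjusted p 2.5e-07, adjusted p = 0.3 with an estimated correlation), COX6C by 1.56. NF-kB targets (10 of 27 fell, 12 over the list alone), immediate early genes (7 of 23 fell, 1 rose), early precursor genes (2 rose and 3 fell of 12), monocyte markers (2 of 13 fell, median −0.11, adjusted p 0.29), chemotaxis, NADPH oxidase and dendritic cell genes were not called as lists. MME again did not differ detectably (log2 −0.04, adjusted p 0.952).

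The 3 imm LDG libraries could not be parted from the 8 mat LDG libraries gene by gene. Granule protein and cell cycle genes, which mark granulocyte precursors, did not differ detectably between them, and neither did MME. Of 11979 genes tested with limma 0 were called, over all genes or over any list alone, and 44 had an unadjusted p under 0.05. In simulations with the spread of mat LDG on both sides, 5.45% of genes with a log2 change of 1 and 50.6% of those with 2 were recovered. MME averaged 67.0 ± 38.1 RPKM in imm and 56.5 ± 40.2 in mat LDG (log2 0.49, SE 0.67), LTF 215.7 ± 90.5 and 552.8 ± 746 (log2 −0.12), and DEFA1, a sequence near identical to DEFA1B and DEFA3, 118 ± 59.2 and 759 ± 1372 (log2 −0.72). As lists, azurophilic granule proteins (median −0.29, adjusted p 0.13), specific granule proteins (−0.08, adjusted p 0.46) and cell cycle genes (−0.11, adjusted p 0.13) were not called. Interferon-stimulated genes lay lower in imm (median −0.62, −0.91 within run 1, −1.69 without the libraries in doubt, adjusted p 1.9e-07, adjusted p = 0.64 with an estimated correlation). Platelet markers (−0.75, −0.38 within run 1, adjusted p 0.00063), ribosomal protein genes (−0.29, adjusted p 3.9e-06) and 5 T cell markers (−0.17, adjusted p 0.022) were also called lower. Called higher were immediate early genes (0.51, adjusted p 1.5e-06), mature receptors (0.44, adjusted p 2.4e-05), Fc receptors (0.31, adjusted p 1e-05), gelatinase granule proteins (0.38, adjusted p 0.0026), chemotaxis genes (0.14, adjusted p 0.005), inflammasome genes (0.17, adjusted p 0.048) and basophil markers (0.49, adjusted p 0.0027). With an estimated correlation none of these was called, the lowest adjusted p being 0.64. Leaving out 1 imm library turned the basophil median to −0.11 (adjusted p 0.54), and leaving out another turned the platelet median to 0.42 (0.08). The interferon call was lost without either of 2 imm libraries, at medians of −0.30 (0.11) and 0.02 (0.76), and that of immediate early genes without 1 of them (0.41). With quantile normalization the calls of chemotaxis (0.13) and inflammasome genes (0.1) were lost. Without the libraries in doubt those of Fc receptors (0.68), gelatinase granule (0.71) and chemotaxis genes (0.57) were lost. The ribosomal protein (0.23) and platelet (0.15) medians then turned positive, and the mature receptor and inflammasome tests reversed direction. Azurophilic granule proteins were called higher (0.47, adjusted p 0.0096).

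CD10-negative LDG had the expression of granulocyte precursors when set against CD10-positive LDG. All tested genes of azurophilic and specific granules, 35 of 39 cell cycle genes and 7 of 13 early precursor genes rose, while 21 of 23 receptor genes of mature neutrophils fell. No list call of this comparison held with an estimated correlation, the lowest adjusted p being 0.058. Most interferon-stimulated genes fell as well, and so did 10 of 27 inflammatory cytokine genes and NF-kB targets. MME, the gene of the sorting marker CD10, fell too. Of 12927 genes tested 4681 were called, 3214 higher and 1467 lower (68.7% higher; 52.6% with size factors, 51.4% with quantile normalization and 56.7% with each library scaled to the same sum, as the median of all genes moved from 0.18 to −0.01, −0.02 and 0.09), and 1031 and 622 of these changed at least 2-fold.

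DEFA1 averaged 7886 ± 1293 RPKM in CD10-negative and 58.9 ± 31.9 in CD10-positive LDG (log2 7.33, adjusted p 9.34e-09), and DEFA1B and DEFA3 rose by 7.32 and 7.06. LTF rose from 30.1 ± 22.4 to 3800 ± 2265 (adjusted p 1.59e-07) and LCN2 from 18.9 ± 14.8 to 2060 ± 1023 (log2 6.92). All 15 azurophilic granule genes (median 6.32, adjusted p 1.6e-18, adjusted p = 0.061 with an estimated correlation) and all 18 specific granule genes (median 5.55, adjusted p 4.6e-20, adjusted p = 0.061 with an estimated correlation) rose. Of 39 cell cycle genes 35 rose (39 over the list alone, median 1.59, adjusted p 1.7e-11, adjusted p = 0.44 with an estimated correlation), with the thymidylate synthase gene TYMS at 23 ± 9.73 against 2.65 ± 3.52 RPKM (log2 3) and TK1 at log2 2.31. Of 13 early precursor genes 7 rose (median 1.02, adjusted p 0.00066, adjusted p = 0.35 with an estimated correlation). They were CEBPE, a transcription factor gene of granule synthesis, from 2.21 ± 0.857 to 89.5 ± 46.3 RPKM (log2 4.71, adjusted p 1.43e-08), CLEC5A (log2 3.30), MYB (log2 3.17), GFI1 (log2 3.04), CEBPA (log2 1.43), CD63 (log2 1.22) and RUNX1 (log2 1.02). FUT4 rose from 5.41 ± 1.63 to 47.3 ± 11.8 RPKM (log2 2.92, adjusted p 8.37e-08). Gelatinase granule genes parted, 7 rising and 7 falling of 16 (median 0.03, adjusted p 0.47): ARG1 (log2 4.50), CD177 (log2 4.19), PADI4 (log2 2.12), CYBB (log2 1.99) and MMP9 (log2 1.97) rose and ALPL (log2 −2.67), MMP25 (log2 −2.22) and FPR1 (log2 −1.92) fell. Ribosomal protein genes rose in 38 of 79 (54 over the list alone, median 0.81, adjusted p 3.8e-06, adjusted p = 0.74 with an estimated correlation), RPLP1 from 448.8 ± 173.6 to 1030 ± 352.6 RPKM (log2 1.25) and RPL36A by 1.16. Within LE and PPAR libraries alone neither RPLP1 (adjusted p 0.0597 and 0.0684) nor RPL36A (0.118 and 0.0562) was called. Oxidative phosphorylation genes rose in 31 of 55 (40 over the list alone, median 0.65, adjusted p 1.9e-05, adjusted p = 0.74 with an estimated correlation), ATP5MC1 by 1.32 (not called within LE, adjusted p 0.115). Protein folding genes rose in 17 of 30 (19 over the list alone, median 0.64, adjusted p 0.00042, adjusted p = 0.74 with an estimated correlation), CANX by 1.46.

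**Figure D3:**
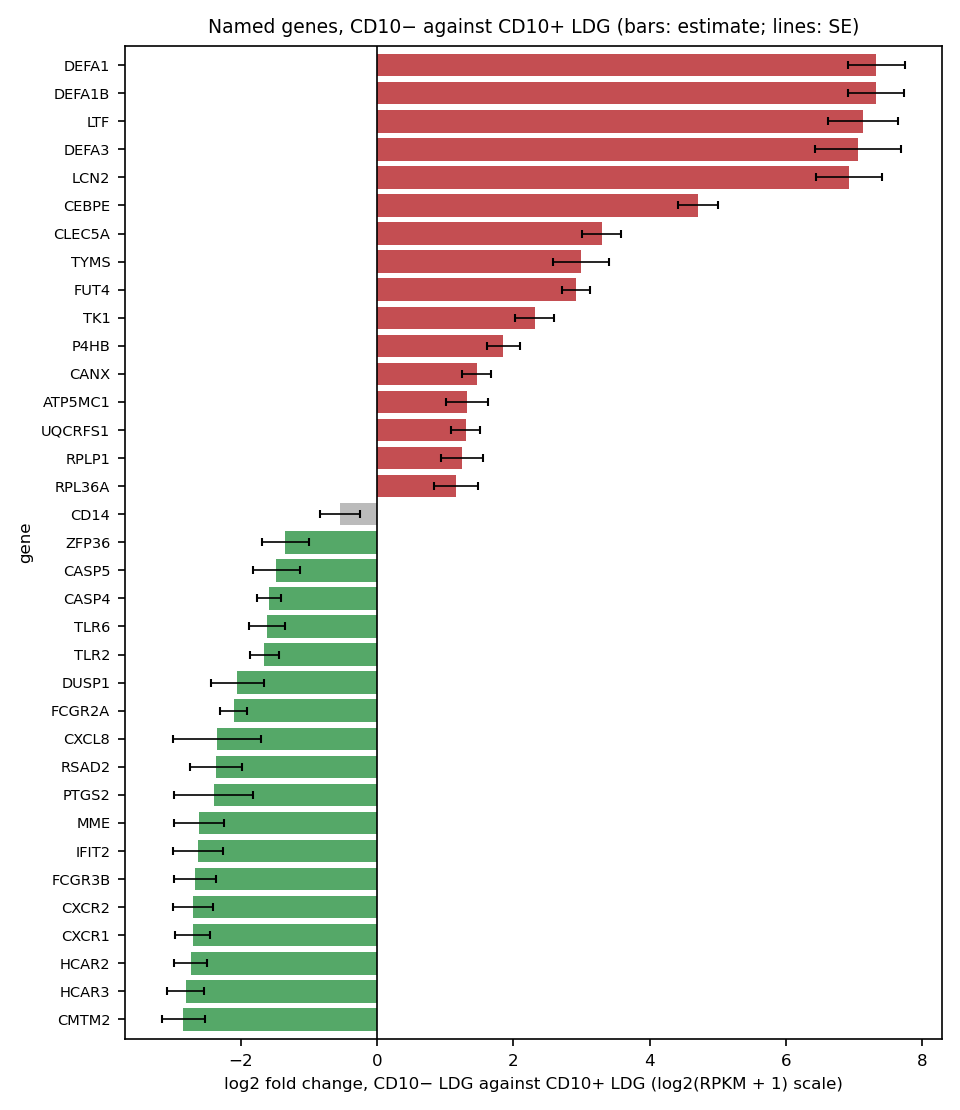
Log2 difference of RPKM + 1 between CD10-negative and CD10-positive LDG (n = 6 each) for selected genes, as bars with lines for the SE. Granule genes such as DEFA1 (7.33) rose and mature receptors such as CXCR2 (−2.70) fell, and CD14, in grey, was not called.

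Receptors of mature neutrophils fell in 21 of 23 (median −1.93, adjusted p 1.7e-22, adjusted p = 0.058 with an estimated correlation), LILRB2 (log2 −0.11) and MGAM (log2 −0.45) not being called. CXCR2 fell from 470.9 ± 132.1 to 75.5 ± 38.9 RPKM, CXCR1 from 272.5 ± 79.8 to 41.6 ± 15.6 (both log2 −2.70) and FCGR3B, a near copy of FCGR3A, from 1171 ± 430.4 to 191 ± 96.6 (log2 −2.67). CMTM2 (log2 −2.84) and the near-identical HCAR3 (log2 −2.81) and HCAR2 (log2 −2.73) were among the largest falls. MME fell from 57.2 ± 31.7 to 8.32 ± 4.75 RPKM (log2 −2.61, adjusted p 8.43e-05). CD14, whose product was also stained in the sort, averaged 298.2 ± 86.2 and 216.7 ± 99.5 RPKM (log2 −0.54, adjusted p 0.166; called with size factors, adjusted p 0.0311). Interferon-stimulated genes fell in 39 of 50 (42 over the list alone, median −1.21, adjusted p 1.7e-22, adjusted p = 0.19 with an estimated correlation), IFIT2 from 526.8 ± 350.3 to 83.3 ± 45.6 RPKM (log2 −2.62, adjusted p 7.07e-05) and RSAD2 by 2.36. NF-kB targets fell in 10 of 27 (11 over the list alone, median −1.12, adjusted p 2.8e-07, adjusted p = 0.44 with an estimated correlation), with PTGS2 at log2 −2.39 and CXCL8 at 156.3 ± 153.4 against 1051 ± 1359 RPKM (log2 −2.35, adjusted p 0.0109). PTGS2 was not called within LE (adjusted p 0.0578) or PPAR libraries alone (0.0533), nor CXCL8 within PPAR (0.107). Immediate early genes fell in 7 of 22 (median −0.48, adjusted p 9.3e-05, adjusted p = 0.54 with an estimated correlation), DUSP1 by 2.05 and ZFP36 by 1.34 (not called within PPAR, adjusted p 0.107). Fc and complement receptors fell in 10 of 20 (median −0.68, adjusted p 0.00025, adjusted p = 0.073 with an estimated correlation), FCGR2A by 2.1, whereas CD59 (log2 1.48), C3AR1 (log2 1.27) and ITGAM (log2 1.16) rose. Inflammasome genes fell in 11 of 20 (median −0.88, adjusted p 1.1e-05, adjusted p = 0.058 with an estimated correlation), CASP4 by 1.58 and CASP5 by 1.47 (not called within LE, adjusted p 0.0822), while NLRC4 (log2 1.83) and IL18 (log2 1.37) rose. Toll-like receptor genes fell in 11 and rose in 4 of 26 (median −0.29, adjusted p 0.0016, adjusted p = 0.44 with an estimated correlation), TLR2 falling by 1.65. The NADPH oxidase list was not called, with CYBB higher and NCF1 lower (log2 −1.20).

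Markers of other blood cells differed little between the 2 sorted LDG groups. T cell markers had a median of −0.28 with 0 of 18 called (adjusted p 0.03, adjusted p = 0.74 with an estimated correlation), a list call lost without the libraries in doubt (−0.18, adjusted p 0.064), at an RPKM of 2 or more (0.1) and with libraries scaled to the same sum (0.054). NK cell, B cell, plasma cell, monocyte, dendritic cell, erythroid, eosinophil and basophil markers and chemotaxis genes were not called as lists. Single genes of these lists did rise: the NK cell gene NKG7 (346.7 against 113.7 RPKM, log2 2.28, adjusted p 0.0115), RNASE2 (log2 3.56), CLC (log2 3) and SLC29A1 (log2 1.92), whereas CCR3 fell by 1.85. The median of 19 platelet markers was −0.07 (adjusted p 0.098; 0.042 with the replicate number as a block, and adjusted p = 0.6 with the block and an estimated correlation), with SELP alone called (log2 −0.39).

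**Figure D4:**
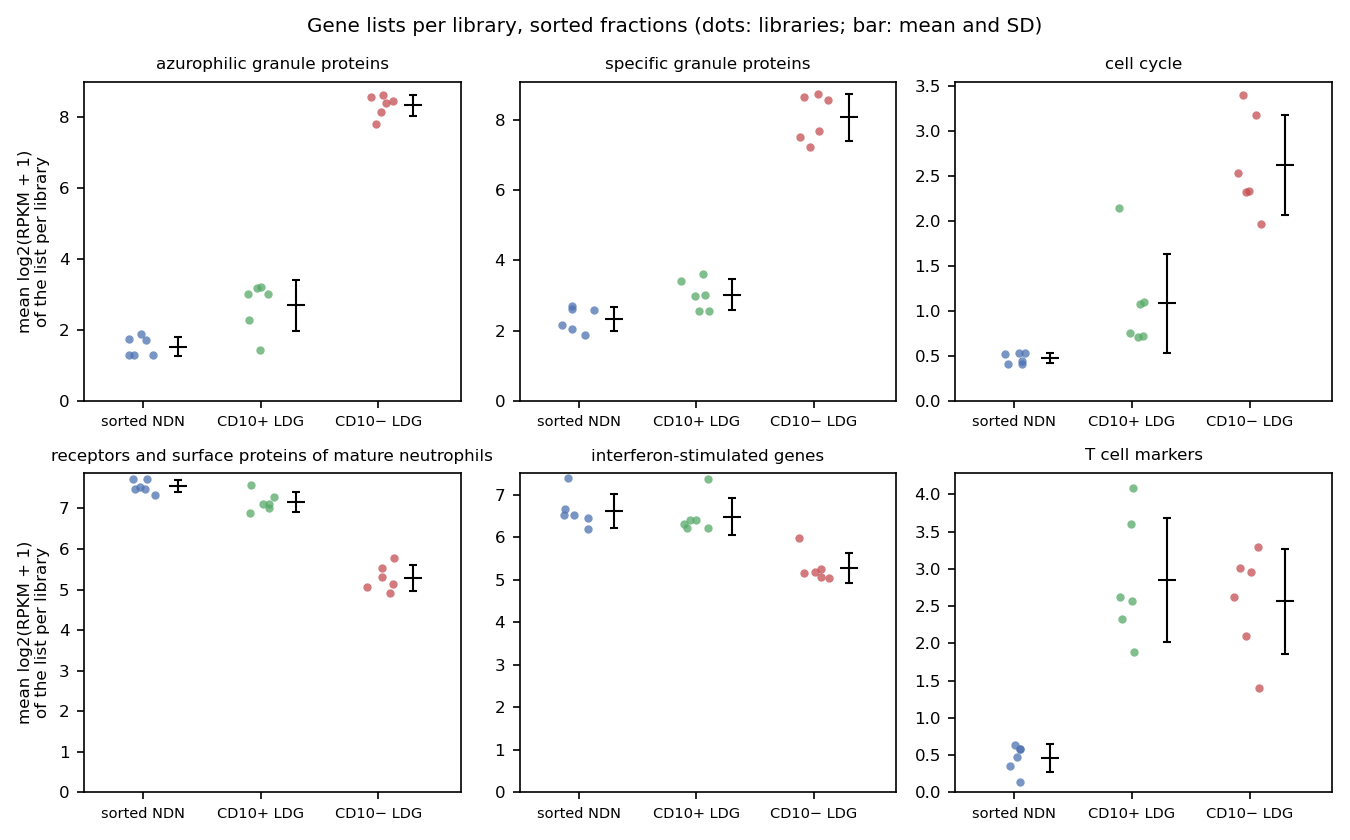
Mean log2(RPKM + 1) of 6 gene lists in sorted NDN, CD10-positive LDG and CD10-negative LDG, with 1 dot per library and bars for the mean and SD. Azurophilic granule genes averaged 1.53, 2.69 and 8.34, and mature receptors 7.55, 7.16 and 5.29.

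Sorted CD10-positive LDG stood above sorted NDN in ribosomal protein genes, in genes of energy metabolism and protein folding, and in markers of T cells, NK cells, B cells and monocytes. None of these list calls held with an estimated correlation, with adjusted p from 0.34 to 0.47. Azurophilic granule and early precursor genes rose far less than in CD10-negative LDG. RNA of these other cells as a source was not tested. Receptors of mature neutrophils were slightly lower, 5 of them by a call. Of 11809 genes tested 4638 were called, 4377 higher and 261 lower (94.4% higher; 73.2% with size factors and 41.3% with quantile normalization, as the median of all genes moved from 0.23 to 0.03 and −0.22), and 2196 of the higher and 3 of the lower genes changed at least 2-fold. With the replicate block, 5274 were higher and 1044 lower (83.5% higher). Ribosomal protein genes rose in 78 of 79 (median 2.96, adjusted p 4.1e-34, adjusted p = 0.34 with an estimated correlation), RPL4 from 3.73 ± 1.23 to 170.9 ± 73.4 RPKM (log2 5.10) and RPL10A by 4.91. Oxidative phosphorylation genes rose in 53 of 55 (54 over the list alone, median 1.19, adjusted p 2.9e-11, adjusted p = 0.41 with an estimated correlation), COX6C by 3.17. Protein folding genes rose in 27 of 30 (29 over the list alone, median 1.37, adjusted p 5.4e-07, adjusted p = 0.41 with an estimated correlation), SSR4 by 2.65 and CALR by 2.51. All 17 T cell markers (median 2.60, adjusted p 1.4e-07, adjusted p = 0.35 with an estimated correlation) and 9 of 11 NK cell markers (median 3.45, adjusted p 0.01, adjusted p = 0.47 with an estimated correlation) rose. So did all 8 B cell markers (median 1.08, adjusted p 0.00033, adjusted p = 0.34 with an estimated correlation) and all 14 monocyte markers (median 2.76, adjusted p 3.2e-07, adjusted p = 0.34 with an estimated correlation). VCAN, abundant in monocytes, averaged 49 ± 28.7 against 0.314 ± 0.179 RPKM (log2 5.07, adjusted p 5.99e-08), CD4 32.6 ± 12.9 against 1.88 ± 2.09 (log2 3.68), and CPVL (log2 4.53), GNLY (log2 4.06; not called within PPAR, adjusted p 0.0579), CD3D (log2 3.60), CD79B (log2 2.73) and CD79A (log2 2.37) rose too. ANXA2 had the largest change, from 0.683 ± 0.205 to 80.5 ± 38.2 RPKM (log2 5.47, adjusted p 2.34e-08).

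Dendritic cell markers rose in 7 of 11 in CD10-positive LDG (median 0.99, adjusted p 0.029, adjusted p = 0.35 with an estimated correlation; 0.066 with the replicate block), CLEC10A by 2.49. Platelet markers rose in 8 of 12 (median 2.06, adjusted p 0.031, adjusted p = 0.47 with an estimated correlation; 0.1 with the replicate block), NRGN by 4.16. Azurophilic granule genes rose in 13 of 14 (median 1.31, adjusted p 0.011, adjusted p = 0.51 with an estimated correlation), DEFA1B by 1.64 and DEFA1 by 1.63, neither called in PPAR libraries alone (adjusted p 0.389 and 0.393). Early precursor genes rose in 9 of 11 (10 over the list alone, median 0.99, adjusted p 0.0024, adjusted p = 0.35 with an estimated correlation), CD81 by 3.53. Specific granule genes (10 of 16 rose, median 0.70, adjusted p 0.43) and cell cycle genes (9 of 18 rose, 10 over the list alone, median 0.83, adjusted p 0.12) were not called as lists. Nor were erythroid markers (4 of 6 rose), eosinophil markers (3 of 7), plasma cell markers (2 of 4) and basophil markers (1 of 3). Mature receptors fell in 5 of 23 (1 over the list alone, median −0.43, adjusted p 4e-09, adjusted p = 0.3 with an estimated correlation): CSF3R, the receptor of G-CSF (log2 −0.61), TNFRSF10C (log2 −0.51), CSF2RB (log2 −0.50), KCNJ15 (log2 −0.49) and C5AR1 (log2 −0.48). In PPAR libraries alone CSF3R (adjusted p 0.171), TNFRSF10C (0.469) and C5AR1 (0.483) were not called, and C5AR1 was not called with no filter either (0.053). Interferon-stimulated genes rose in 2 and fell in 1 of 50, EPSTI1 by 0.40, a call lost with no filter (adjusted p 0.069) and within LE (0.0813) and PPAR (0.533) (0 over the list alone, median −0.28, adjusted p 1.3e-07, adjusted p = 0.45 with an estimated correlation). Called lower as lists were NF-kB targets (median −0.27, adjusted p 0.00094, adjusted p = 0.47 with an estimated correlation) and Fc receptors (−0.17, adjusted p 0.0014, adjusted p = 0.3 with an estimated correlation). So were inflammasome genes (−0.07, adjusted p 0.015, adjusted p = 0.34 with an estimated correlation) and gelatinase granule genes (−0.10, adjusted p 0.029, adjusted p = 0.35 with an estimated correlation). These 4 calls and that of interferon-stimulated genes were lost with quantile normalization. The gelatinase call was also lost with size factors (adjusted p 0.058), no filter (0.076) and an RPKM of 2 or more (0.089), that of inflammasome genes with no filter (0.051) and an RPKM of 2 or more (0.063). With 1 fit over all groups the calls of dendritic cell (0.07) and platelet markers (0.054) were lost, and in PPAR libraries alone that of azurophilic granule genes (0.074). HNRNPH2 (42.3 ± 5.46 to 12.7 ± 5.94 RPKM, log2 −1.75, adjusted p 2.48e-05) had the largest fall, and IRS2 also fell (log2 −0.98; not called with no filter, adjusted p 0.0593, or within LE, 0.196, or PPAR, 0.113). MME was lower without a call (57.2 ± 31.7 against 79.3 ± 31.8 RPKM, log2 −0.54, adjusted p 0.256), and was called with the replicate block (adjusted p 0.0129). CD14 rose from 179.7 ± 61.2 to 298.2 ± 86.2 RPKM (log2 0.76, adjusted p 0.0295), a call lost with size factors (adjusted p 0.12), with no filter (adjusted p 0.0604) and within each donor label. FUT4 rose from 2.56 ± 1.48 to 5.41 ± 1.63 (log2 0.88, adjusted p 0.00759), a call lost with quantile normalization (adjusted p 0.259) and in PPAR libraries alone (adjusted p 0.37).

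CD10-negative LDG had, against sorted NDN, precursor expression together with higher ribosomal protein genes and T cell, NK cell and monocyte markers. No list call held with an estimated correlation, the lowest adjusted p being 0.11. Granule genes were the largest rises, and ALPL, NLRP6, CXCR2, FCGR3B and PGGHG the largest falls. Of 12279 genes tested 8827 were called, 6582 higher and 2245 lower (74.6% higher; 60.7% with size factors and 45% with quantile normalization, as the median of all genes moved from 0.52 to 0.21 and −0.16), and 4377 and 980 of these changed at least 2-fold. DEFA1B averaged 7804 ± 1402 against 15.2 ± 5.24 RPKM (log2 8.96, adjusted p 1.96e-13), and DEFA1 (log2 8.96), LTF (log2 8.86) and LCN2 (log2 8.51) followed. All 15 azurophilic granule genes rose (median 7.67, adjusted p 1.1e-07, adjusted p = 0.19 with an estimated correlation), as did all 18 specific granule genes (median 6.26, adjusted p 1.6e-06, adjusted p = 0.36 with an estimated correlation). All 36 cell cycle genes (median 2.28, adjusted p 8e-06, adjusted p = 0.43 with an estimated correlation) and 11 early precursor genes (median 3.30, adjusted p 0.00098, adjusted p = 0.3 with an estimated correlation) rose. The changes included CEBPE at log2 5.18, TYMS at 4.31, CLEC5A at 4.02 and MCM3 at 3.59. Mature receptors fell in 22 of 23 (median −2.41, adjusted p 1.3e-16, adjusted p = 0.11 with an estimated correlation), CXCR2 by 3.23 and FCGR3B by 3.22, and the secretory vesicle gene ALPL fell by 3.39, the inflammasome sensor gene NLRP6 by 3.26 and PGGHG by 3.16. Interferon-stimulated genes fell in 42 of 50 (median −1.49, adjusted p 1.7e-17, adjusted p = 0.3 with an estimated correlation), while the sialoadhesin gene SIGLEC1 (log2 1.94) and BST2 (log2 0.52) rose. NF-kB targets fell in 13 of 27 (median −1.24, adjusted p 1.6e-06, adjusted p = 0.38 with an estimated correlation), CXCL8 by 2.88 and OSM by 2.73. Immediate early genes fell in 8 of 22 (median −0.32, adjusted p 0.00094, adjusted p = 0.43 with an estimated correlation), DUSP1 by 2.48, and inflammasome genes in 11 of 20 (median −1.02, adjusted p 7.1e-05, adjusted p = 0.11 with an estimated correlation), CASP5 by 2.14. Fc receptors fell in 10 and rose in 5 of 20 (median −0.56, adjusted p 0.00036, adjusted p = 0.11 with an estimated correlation). Toll-like receptor genes fell in 11 and rose in 9 of 26 (median −0.23, adjusted p 0.011, adjusted p = 0.41 with an estimated correlation). All 79 ribosomal protein genes rose (median 3.87, adjusted p 1.2e-17, adjusted p = 0.38 with an estimated correlation), RPL4 by 6.05. So did 54 of 55 oxidative phosphorylation genes (median 2.05, adjusted p 1e-09, adjusted p = 0.36 with an estimated correlation) and 29 of 30 protein folding genes (median 2.09, adjusted p 3.8e-06, adjusted p = 0.36 with an estimated correlation), with COX6C at log2 4.21 and SSR4 at 3.73. T cell markers rose in 16 of 16 (median 2.29, adjusted p 0.0062, adjusted p = 0.5 with an estimated correlation) and NK cell markers in 9 of 10 (median 3.48, adjusted p 0.036, adjusted p = 0.47 with an estimated correlation). Monocyte markers rose in 13 of 14 (median 2.84, adjusted p 0.0062, adjusted p = 0.47 with an estimated correlation), VCAN by 5.38. Among NK and T cell markers NKG7 rose by 6.4 and CD4 by 3.93. The T cell list call was lost at an RPKM of 2 or more (adjusted p 0.078) and that of NK cell markers with 1 fit over all groups (0.13). Lists of B cell (8 of 8 rose, adjusted p 0.1), dendritic cell (6 of 10 rose, 0.45) and platelet markers (8 rose and 2 fell of 12, 0.74) were not called, although that of B cell markers was under 5 alternatives. With quantile normalization the calls of Fc receptors (0.13), immediate early genes (0.17) and toll-like receptor genes (0.26) were lost. MME fell by 3.15 (adjusted p 4.08e-07), FUT4 rose by 3.81 and CD14 was not called (log2 0.22, adjusted p 0.537). With the replicate block, the 4 changes given above were the only ones in sorted calls of named genes or lists. The block moved no total of called genes there by more than 1.5 times.

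The donor labels PPAR and LE parted few genes when all libraries were used, but leaving out 1 library gave 0 to 719 calls in CD10-positive and 0 to 93 in CD10-negative LDG. Of 14649 genes tested with limma, 0 differed in sorted NDN (318 at an unadjusted p under 0.05), 2 in CD10-positive LDG (3207) and 0 in CD10-negative LDG (1134), with 3 libraries per label in each, and 0 had a CD10 difference that changed with the label (466). The 2 genes were TIMM21, a mitochondrial import gene, at 0.513 ± 0.139 RPKM in PPAR and 2.15 ± 0.515 in LE (log2 −1.05, SE 0.15, adjusted p 0.022), and MIR4746. The latter, singled out after its values were seen, stood at 1.39 ± 0.368 RPKM in PPAR and listed at 0 in all 3 LE libraries (adjusted p 0.00363). The call of TIMM21 was lost under 5 alternatives, such as a pseudocount of 0.1 (adjusted p 0.091) and size factors (adjusted p 0.0692). It was also lost in 3 of the fits that left out 1 CD10-positive library, and the adjusted p of these 8 settings ran from 0.0568 to 0.251. In CD10-positive LDG, 5 lists were called lower in PPAR. These were ribosomal protein genes (median −0.76, adjusted p 2.8e-07, adjusted p = 0.59 with an estimated correlation) and protein folding genes (−0.75, adjusted p 5.9e-07, adjusted p = 0.48 with an estimated correlation). The others were NK cell markers (−1.53, adjusted p 9.9e-06, adjusted p = 0.48 with an estimated correlation), T cell markers (−1.27, adjusted p 3.6e-05, adjusted p = 0.55 with an estimated correlation) and oxidative phosphorylation genes (−0.55, adjusted p 2.1e-05, adjusted p = 0.59 with an estimated correlation). Over their own list alone 7, 18, 11, 12 and 13 members passed. NF-kB targets were called higher in PPAR in NDN (0.43, adjusted p 2.7e-06, adjusted p = 0.7 with an estimated correlation). So they were in CD10-positive (0.69, adjusted p 9.6e-10, adjusted p = 0.48 with an estimated correlation) and CD10-negative LDG (0.70, adjusted p 8.1e-07, adjusted p = 0.59 with an estimated correlation). Interferon-stimulated genes were called higher in the 3 fractions in the same order (0.27, 0.27 and 0.29, adjusted p 8e-11, 1.1e-11 and 8.7e-09, adjusted p = 0.7, 0.48 and 0.64 with an estimated correlation). Mature receptors lay higher in PPAR in CD10-negative LDG (0.55, adjusted p 7.4e-11, adjusted p = 0.17 with an estimated correlation).

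The 2 tables gave opposite pictures of the same nominal contrast. Bulk LDG had lower T cell markers and ribosomal protein genes than bulk NDN, and sorted CD10-positive LDG had higher ones than sorted NDN. Across 10129 genes, which are not independent replicates, the 2 differences correlated at r = −0.48 (jackknife SE 0.18, Spearman −0.40), and −0.57 within run 1. Of the genes called in both, 84 were higher in both (59 expected by chance) and 5 lower in both (26.5 expected), and 977 had opposite directions. Platelet and azurophilic granule lists were called higher in LDG in both tables at the preset correlation. In the sorted table both calls were lost with an estimated correlation (adjusted p 0.47 and 0.51), and that of platelet markers with the replicate block (0.1). In bulk LDG against lupus NDN the azurophilic call was lost with an estimated correlation (0.1), and the platelet call with the block and an estimated correlation (0.099). The difference of imm from mat LDG had r = −0.30 with that of CD10-negative from CD10-positive LDG across 10954 genes (jackknife SE 0.47, Spearman −0.36), a sign that turned without the libraries in doubt (0.09). The 2 NDN groups lay apart in the same way, at ribosomal means of 165 ± 85.3 RPKM in bulk lupus NDN and 27 ± 4.22 in sorted NDN, across tables that were normalized separately.

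**Figure D5:**
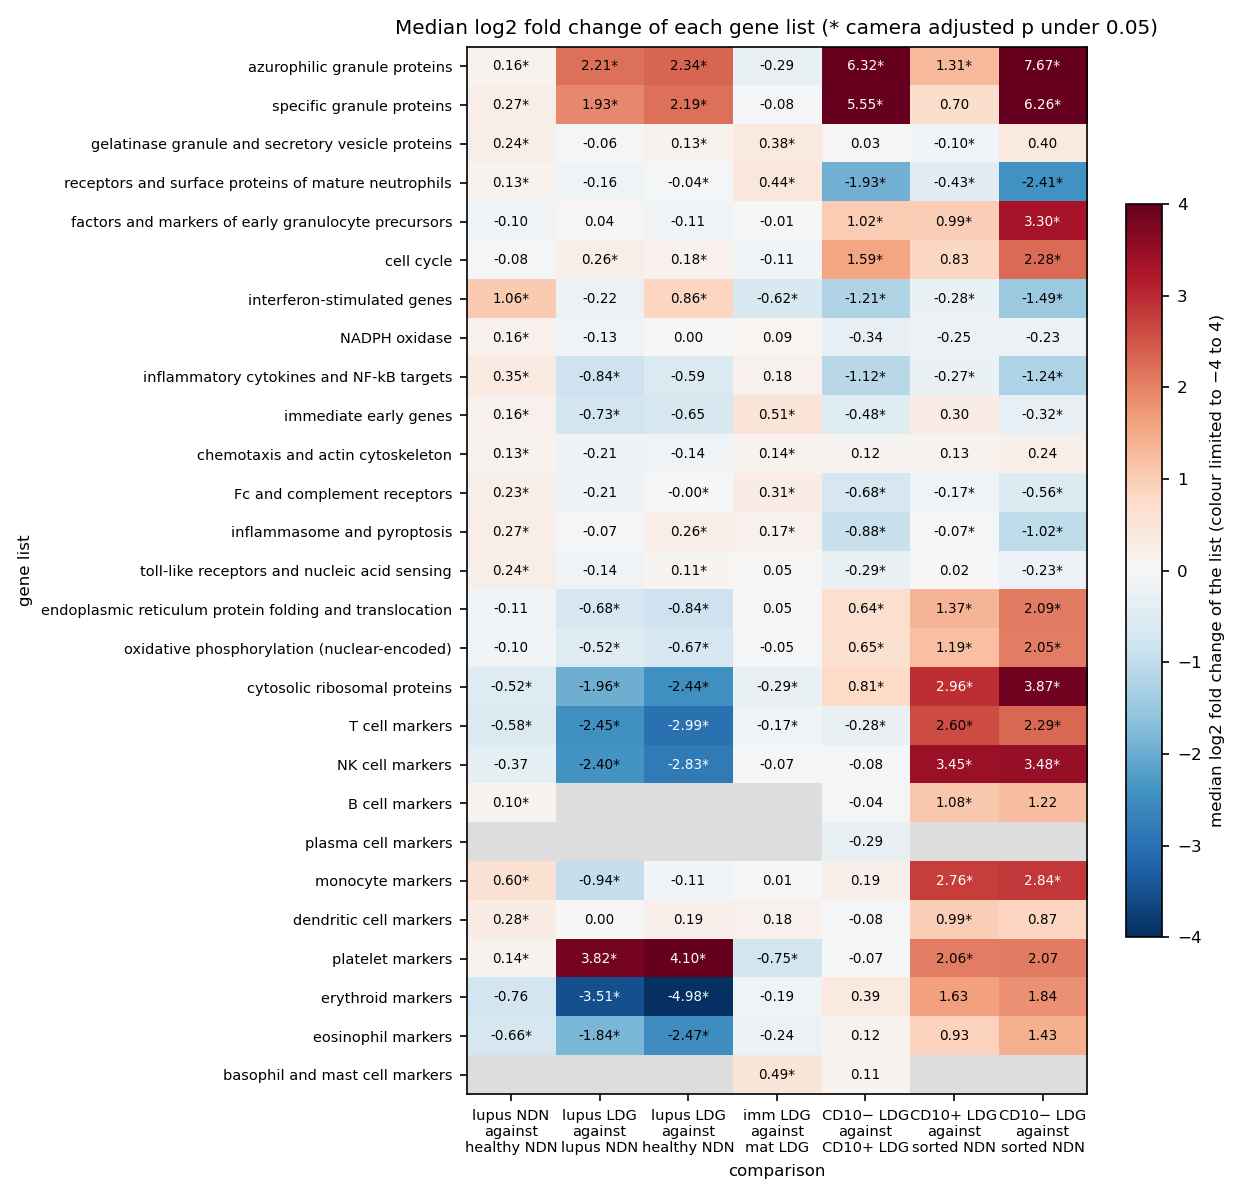
Median log2 difference of RPKM + 1 per gene list (vertical) in 7 comparisons (horizontal), with colours limited to −4 to 4, asterisks for lists called at a preset correlation and grey for lists with fewer than 5 tested genes. Ribosomal protein genes had a median of −1.96 in bulk LDG against lupus NDN and 2.96 in CD10-positive LDG against sorted NDN.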

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

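All tests of explanations given here were chosen after the results they address were seen. In groups of 4 to 10 libraries, the gap between the highest or lowest library and its neighbour was compared with the range of the group, and a share above Dixon's 95% bound marks a library far from the others. Chance gives about 1 such mark in 20. Of 132 list scores and library measures 11 passed the bound, and of 277 pairs of a named gene and a group 18 did.

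Among list scores, the highest library stood apart in CD10-positive LDG for cell cycle genes (72.6% of the range), eosinophil markers (64.9%), interferon-stimulated genes (83.1%) and plasma cell markers (79.9%), in CD10-negative LDG for interferon-stimulated genes (78.7%) and plasma cell markers (81.5%), and in mat LDG for chemotaxis and actin genes (52.6%), erythroid markers (67.4%) and NADPH oxidase genes (56.4%). In mat LDG the highest library also stood apart in mitochondrial rRNA (60.5%), and in CD10-negative LDG the lowest in the percentage of genes at 0 (83.6%). Among named genes, the highest mat LDG library stood apart in ALOX15 (79%), HBA1 (78%), HBA2 (71.2%), HBB (80%) and PRSS33 (75.6%). In sorted NDN the highest library stood apart in FUT4 (63.4%), GP1BB (70.6%), IFIT2 (68.3%) and IFIT3 (73.8%) and the lowest in ADAM8 (63.9%) and RPL4 (73.6%). In CD10-positive LDG the highest stood apart in FCGR2A (73.1%), IFIT2 (64.6%) and IFIT3 (72.7%) and the lowest in TNFRSF10C (64.3%), and in CD10-negative LDG the highest in CXCL8 (66.5%) and the lowest in COX7C (62.8%) and DEFA3 (80%). Near-identical copies (HBA1 and HBA2, DEFA1 and DEFA3) and members of 1 list do not pass the bound independently.

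Ribosomal protein transcripts were lower in bulk LDG and higher in sorted LDG than in the NDN beside them. The tables argue against the RPKM scaling, since quantile normalization left −1.71 in the bulk and 2.82 in the sorted table. RNA of T cells in the bulk NDN may account for the bulk part: within groups the ribosomal mean rose by 10.5 ± 2.7 (SE) RPKM per RPKM of T cell markers in 22 NDN libraries (10.9 ± 3.3 in 17 of run 1), which gives 69.9 RPKM (20.7 to 119) at the marker level of LDG, where 50.2 was observed and 108 would be halfway. RNA of T cells, NK cells, B cells and monocytes may likewise account for the sorted part, with 77.6 RPKM expected (10.5 to 145), 27 observed in sorted NDN and 99.4 halfway, a wide interval from 6 libraries that were sorted for CD10 and stained for CD14 and CD15. These slopes were picked after several measures and scales had been tried. Monocyte markers gave no positive slope within sorted NDN, and a difference of the granulocytes themselves stays open. Immaturity of the bulk LDG cannot be told apart, because the fall (median −1.96, interval over libraries −2.59 to −1.24) is the pattern itself and RNA of other cells in the NDN would hide a rise.

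Platelet transcripts were higher in bulk LDG than in lupus NDN. The tables argue against the sequencing run, with a median of 3.45 within run 1 against 3.82 over both, and against expression by CD10-negative granulocytes, whose median against CD10-positive LDG was −0.0661 (−0.818 to 0.674). RNA of platelets in the bulk LDG is a candidate source. The 17 markers rose and fell together across LDG libraries, with a median pairwise correlation of 0.95. Random lists of like level, not matched on spread, had a 95th percentile of 0.204. PPBP averaged 319.9 and PF4 246.6 RPKM in LDG. Platelets bound to LDG and platelets carried along with the mononuclear layer were not told apart by any test.

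Interferon-stimulated genes were higher in lupus NDN than in healthy NDN. The sequencing run alone is argued against, with a median of 0.952 within run 1 against 1.06 over both. Whether RNA of monocytes in lupus NDN is the source cannot be told apart from the neutrophils' own expression, because the difference in score of 1.21 became 0.729 with the monocyte score as a term, with an interval of −0.386 to 1.84 that holds both 0 and the full difference (0.604 would be halfway). Monocyte markers averaged 3.01 ± 0.836 in lupus and 2.31 ± 0.33 in healthy NDN, and VCAN 8.10 and 1.39 RPKM. Lupus itself stays among the open explanations.

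Random splits of the same libraries showed which counts chance can give. The 100 splits include the real one, so the smallest possible share is 1 of 100. For LDG against lupus NDN 3 of 100 had as many called genes, with 1353 in the real split and 1602 in the highest other. Few splits reached the real count there, but chance is not excluded. No other split drawn reached it for LDG against healthy NDN (2674 in the real split and 454 in the highest other) or CD10-negative against CD10-positive LDG (4681 and 1414). The same held for CD10-positive LDG (4638 and 3594) and CD10-negative LDG against NDN (8827 and 1). Chance is an unlikely source of these last counts. Among the 32 splits that part all pairs of the sorted table the real split had the most, the highest others giving 1, 2373 and 5403. Chance cannot be excluded for lupus against healthy NDN, where 38 of 100 splits gave as many genes at an unadjusted p under 0.05 (725 and 3025), or for imm against mat LDG, where 99 of 100 did (44 and 4323). Other splits with several times the real number point to a structure of the libraries, and what it follows was not tested. For PPAR against LE the 10 splits are too few for a share under 0.05: 5 gave as many in NDN (318 and 572), 2 in CD10-positive LDG (2 called, 17 in the highest other), 5 in CD10-negative LDG (1134 and 2707) and 4 for the interaction (466 and 929).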

How the results depend on the processing

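The alternative without the libraries in doubt, the agreement between tables within run 1 and that agreement without each library were chosen after the data were seen. Over the comparisons, 2113 list results and 2219 named-gene results kept their direction and side of the threshold across the alternatives, 79 and 133 lost their call, 52 and 2 gained one and 27 and 9 reversed. For lists the medians are printed, and a reversal is that of the list test. Run 2 alone, with 6 bulk libraries, gave 18 of the list reversals and all 9 gene reversals. Its counts were 2 for lupus against healthy NDN, 0 for LDG against lupus NDN and 490 for LDG against healthy NDN (451 higher and 39 lower, the reverse balance), and imm against mat LDG could not be run, as no imm library was in run 2. Its reversed medians were, for lupus against healthy NDN, azurophilic granule −0.201, immediate early −0.37, B cell −0.516 and platelet −0.171. For LDG against lupus NDN they were HBA2 2.02, HBB 2.08, COX6C 0.365, COX7C 0.141, CPVL 1.05, gelatinase granule −0.768, mature receptors −1.41, interferon −1.53, Fc receptors −0.828, inflammasome −0.547, toll-like receptors −0.535, monocyte −0.153, erythroid 1.05 and eosinophil 0.0165. For LDG against healthy NDN they were HBA2 1.02, HBB 1.09, HBA1 1.01, IFI44L −0.723, mature receptors −0.656, interferon −0.366, Fc receptors −0.384, toll-like receptors −0.3 and erythroid 0.677. In both, 1 mat LDG library stood for all LDG and was assumed to vary like the other groups. It was in doubt (mitochondrial rRNA 42587 RPKM), so run and library cannot be told apart. Without the libraries in doubt imm against mat LDG had 1 called gene, azurophilic granule 0.474, mature receptors 0.122, inflammasome −0.0782, ribosomal 0.229 and platelet 0.152 were reversed list tests, and the agreement of imm against mat with CD10-negative against CD10-positive LDG was 0.0865. Without a filter the cell cycle list turned to 0.00754 in lupus against healthy NDN, and there were 5 calls for PPAR against LE in CD10-positive and 16 in CD10-negative LDG. With an RPKM of 2 or more, which tests fewer genes, the counts were 651 for LDG against lupus NDN, 1457 for LDG against healthy NDN (early precursors −0.314), 2533 for CD10-positive LDG against NDN and 0 for PPAR against LE in CD10-positive LDG. Fewer libraries gave 450 and 1618 for imm LDG against lupus and healthy NDN, 1729 in LE and 2311 in PPAR for CD10-negative against CD10-positive LDG (49.3% and 77.5% higher), and 2180 in PPAR for CD10-positive LDG against NDN. Scaling each library to the same sum gave 1 call for lupus against healthy NDN and 1 for the interaction. For PPAR against LE in CD10-positive LDG there were 1 with a pseudocount of 0.1, 1 with size factors, 1 with quantile normalization, 4 without trend or robust and 0 with only its 6 libraries, and the interaction had 1 with a pseudocount of 0.1. Leaving out 1 library at a time gave 0 to 1 calls for imm against mat LDG (basophil −0.11 to 0.839 and platelet −1.65 to 0.422, each reversed without 1 of the imm libraries), 0 to 2 for PPAR against LE in NDN, 0 to 719 in CD10-positive and 0 to 93 in CD10-negative LDG, and 0 to 2 for the interaction. Of 150 list calls at the preset correlation, 6 held with an estimated one, and none of these 6 did with the replicate block as well. The replicate block gave 1474 calls for LDG against lupus NDN and 2936 against healthy NDN. There it joins different people, so a lost call says little. Beyond the settings that test fewer genes or libraries, the cause was not tested. Depth limits the lowest values most, since a shallow library lists weakly expressed genes at 0, and relative depth was lower in mat LDG (median 0.397) than in healthy NDN (0.607).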

Other observations

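The test of granule shares was chosen after the result was seen. Mitochondrial rRNA, which poly(A) selection should mostly leave out, had medians of 6254 RPKM in healthy NDN, 5494 in lupus NDN, 10268.5 in mat and 8826 in imm LDG, and 895.5, 1355 and 1521 in sorted NDN, CD10-positive and CD10-negative LDG, in tables that were normalized separately. The 10 most abundant genes held medians of 18.6%, 21.4%, 24.75% and 21.4% of all RPKM in the bulk groups and 17.55%, 14.5% and 21.45% in the sorted groups.

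One hypothesis was that a single minor share of CD10-negative cells in the bulk LDG accounts for their granule transcripts. It needs every granule list to give the same share of the excess seen in CD10-negative LDG. The shares were 6.84% (0.938 to 16.3) for 15 azurophilic granule genes, 14% (3.46 to 30.6) for 18 specific granule genes and 10.8% (1.2 to 29.8) for 30 cell cycle genes, from levels set across tables that were normalized separately. The ratio of the specific to the azurophilic share was 2.04, with an interval of 0.88 to 8.18 that holds 1, so a single share may hold but was not shown to.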
